A study of Homo sapiens with 4 samples.

How the data were processed

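RNA sequencing of 4 libraries was used, 1 per group: MDA-MB-231 and BT549 cells, each as control in normal medium and after Lespedeza bicolor root at 5 µg/mL for 48 h. Whether the control received the solvent of the root material is not stated. Per the submitters' processing notes, reads were trimmed with cutadapt (1.9), aligned with HISAT2 (2.0.4), deduplicated by molecular identifiers with UMI-tools and quantified with StringTie (1.3.4d), with DESeq2 and edgeR named for differential expression. Libraries were poly(A)-selected and strand-specific. The notes name a mouse build, mm9, while all 35995 gene IDs are human, 34118 of them are in GENCODE 29 and 33994 lie on the GENCODE chromosome within 100000 bases of its position, so positions were read as GRCh38. Whether counting used the strand is not stated, so counts of genes that overlap another gene on the opposite strand are uncertain.

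The deposited table holds 2 units. The authors' estimated counts are whole numbers per gene and were used for every test. The authors' FPKM values were used as an alternative only. Among genes with a single transcript of at least 1000 bases, 41.9 to 43.9% of values from 1 to 16 fell on multiples of 4, against 25% if even, so 1 fragment was taken as 4 units wherever counting error is given. The plan written before the files were opened had assumed plain counts, and the values divided by 4 were therefore added as an alternative. The table also holds 6 columns of 3 libraries that belong to no sample here and whose names give Huh7, a liver cancer cell line; they were not used.

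Library totals ranged from 52.7 M to 60.7 M units, about 13.2 M to 15.2 M fragments. Intervals of ratios are exact conditional binomial intervals at the 95% level on fragments. A gene at 0 was set against a floor of 3 fragments per library, or 12 units, for which a bound is given. Intervals and bounds cover counting error only. Of the genes, 4579 had 0 units in all 4 libraries and 9427 rows, with 0.89% of units, had no gene name.

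Counts were analysed in R (4.3.3) with edgeR (4.0.16): genes passing filterByExpr by treatment group (19927), TMM scaling, and a quasi-likelihood fit with cell line as block and treatment as the tested term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The lines are the replicates, which leaves 1 residual degree of freedom. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples only. DESeq2 (1.42.0) and limma-voom (limma 3.58.1) were run on the same design. Within a line, log2 fold changes of CPM with a prior count of 2 were computed for genes with a mean of at least 5 CPM and counted at 2-fold, with no p-value. Tested on simulated data with the estimated spread, edgeR recovered 80% of 2-fold and 98% of 4-fold changes across lines, with 9 unchanged genes among 187 called. The simulated fold was the same in both lines, so these rates do not cover genes whose response differs in size between lines. Each gene was drawn at the average spread for its expression, and in independent units rather than fragments of 4 units. Recovery in the real data, where genes of like expression differ in spread, can therefore be lower, and the rates do not show that few shared changes exist. The 2-fold counts within a line then included 76 unchanged genes in MDA-MB-231 and 109 in BT549, and 0 at 0.1 of that spread. For the list test, 5 lists drawn from these simulated counts were raised a further 1.5-fold, and camera over 18930 genes gave a p under 0.05 to those 5 and to 0% of 200 unchanged lists. The simulated genes were drawn independently, so these rates do not cover real lists whose members move together.

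Gene lists, the naming rule, thresholds and most of the other settings tried were chosen before the data were examined. The 40 lists were tested with camera (preset correlation 0.01, and estimated) and fry, and within each line their medians were ranked among 10000 random lists matched on mean expression. Genes are named by rule, and only those with a gene symbol: the 12 with the largest smaller change of the 2 lines in each direction, the 8 with the largest change per line and direction, the 8 with the largest difference between lines each way, up to 4 examples per list, and fixed identity markers. FTH1 and the genes described last, under other observations, were chosen after their values were seen. Some genes that the rule takes are not reported here. Length and GC trends were removed by loess (span 0.4). The other settings chosen then were DESeq2 size factors, library totals, other filters and prior counts, FPKM, no block, other tools and each line alone. Division by 4, robust empirical Bayes, exclusion of overlapping or noncoding genes, length and GC correction and Gene Ontology terms were added after the data were seen. Figures were drawn with Python (3.11.15), pandas (2.3.3) and matplotlib (3.10.9).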

Results

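RNA of 2 human triple-negative breast cancer cell lines, MDA-MB-231 and BT549, was sequenced after culture in normal medium (control) or for 48 h with Lespedeza bicolor root, a legume shrub material, at 5 µg/mL (treated). Each of the 4 groups held 1 library, so no value within a line has a replicate. The deposited table gives estimated counts per gene that summed to 60685231 in the control and 58503262 in the treated MDA-MB-231 library, and to 52722408 and 53023380 in the control and treated BT549 libraries. Low values clustered at multiples of 4, so 1 sequenced fragment was worth about 4 deposited units, and the libraries held about 15.2 M, 14.6 M, 13.2 M and 13.3 M fragments in the same order. Counts below are deposited units. Fold changes are of CPM, counts scaled to a common library size, treated over control, and their 95% intervals are exact conditional binomial intervals on fragments, which cover counting error and not the spread between cultures. Coordinates are those of the deposited table, which match human GRCh38.

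Marker genes fixed beforehand were compared between the lines. CDKN2A, a cell cycle inhibitor gene deleted in MDA-MB-231, had 8 and 0 units in the control and treated MDA-MB-231 libraries and 14497 and 12924 in BT549. RB1, a tumor suppressor gene, had 1420 units in control BT549 against 4092 in control MDA-MB-231, and it overlaps opposite-strand genes with up to 1498 units. The estrogen and progesterone receptor genes ESR1 and PGR had at most 8 units in any library, and ERBB2 had between 3482 and 7172. Across both treatments 9955 of 19927 genes differed between the lines by edgeR's quasi-likelihood test at an adjusted p under 0.05, 4849 higher and 5106 lower in BT549. Among them MKI67, a proliferation marker, was lower in BT549 by a log2 difference of -1.63 (SE 0.16, edgeR adjusted p = 0.00124), and CD274, which encodes the checkpoint ligand PD-L1, by -2.63 (SE 0.16, edgeR adjusted p = 3.2e-04).

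The main question was what treatment did in both lines. The list with the largest medians in both lines was that of the aryl hydrocarbon receptor, genes that this sensor of planar aromatic compounds switches on. CYP1A1 (ENSG00000140465; chromosome 15, 74719542 to 74725536), which encodes a cytochrome P450 that oxidizes such compounds, went from 76 to 2479 units in MDA-MB-231, a ratio of 33.1 (interval 21.6 to 56.9), and from 89 to 682 in BT549, a ratio of 7.36 (4.83 to 12.4). CYP1B1, a related cytochrome P450 gene (ENSG00000138061; chromosome 2, 38066973 to 38076154), had ratios of 6.07 (5.74 to 6.42) and 1.61 (1.55 to 1.67), TIPARP, a poly-ADP-ribose polymerase gene, of 3.07 and 1.70. AHRR, the receptor's repressor gene, had a ratio of 5.08 (2.35 to 14.3) in MDA-MB-231 and a log2 change of 0.97 (ratio interval 1.77 to 2.16) in BT549. AHRR shares its strand and position with a read-through gene, and CYP1B1 with a noncoding gene, so both counts are uncertain by the share of such reads. For CYP1B1 in MDA-MB-231 that share was small: it held 5885 of 5893 same-strand units in the control and 34275 of 34316 in the treated library. Of the 9 measured members 8 were higher in both lines and none was lower in both, with medians of 1.64 and 0.69 on the log2 scale. The list was called higher by camera with a preset correlation (adjusted p = 9.0e-18; adjusted p = 0.699 with an estimated correlation).

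Lipid synthesis genes were lower in both treated lines. SCD (ENSG00000099194; chromosome 10, 100347233 to 100364826), the desaturase that makes monounsaturated fatty acids, went from 30285 to 4553 units in MDA-MB-231, a ratio of 0.157 (0.147 to 0.167), and from 91537 to 24066 in BT549, a ratio of 0.257 (0.250 to 0.264). SREBF1, which encodes the transcription factor that drives these enzymes (ENSG00000072310; chromosome 17, 17810399 to 17836986), had ratios of 0.244 and 0.529, FADS2, a polyunsaturated fatty acid desaturase gene (ENSG00000134824; chromosome 11, 61792980 to 61867354), of 0.494 and 0.460, and ACACA, the acetyl-CoA carboxylase gene, of 0.486 and 0.691. FADS2 overlaps FEN1 on its strand and FADS1, with up to 10643 units and log2 changes of -0.51 and -0.33, on the opposite strand, so its counts are uncertain. SREBF1 overlaps RAI1 on the opposite strand, with up to 5102 units and log2 changes of -0.22 and 0.02, so its counts are uncertain too. Of the 15 members of the fatty acid list 13 were lower in both lines and 1 was higher in both, with medians of -0.51 and -0.33 (camera adjusted p = 1.7e-27; adjusted p = 0.699 with an estimated correlation). In the cholesterol synthesis list 16 of 23 members were lower in both lines, with medians of -0.30 and -0.21 (camera adjusted p = 4.2e-13; adjusted p = 0.699 with an estimated correlation). Its examples were INSIG1, a sterol-regulated brake on the pathway, with log2 changes of -0.84 and -0.57, and STARD4, a sterol transfer protein gene, with -0.74 and -0.57.

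Target lists of the factors NRF2, ATF4 and NF-kB had higher medians in both treated lines. The heat shock and endoplasmic reticulum chaperone lists, given below, were not called. HMOX1, heme oxygenase (ENSG00000100292; chromosome 22, 35380361 to 35394214), had ratios of 2.21 (1.81 to 2.71) and 1.71 (1.66 to 1.77), SQSTM1, an autophagy receptor gene, of 2.02 and 1.44, PIR of 2.04 and 1.43, and ABCC3, an efflux pump gene, of 1.67 and 1.5. Of the 25 targets of the antioxidant factor NRF2 17 were higher in both lines and 1 lower in both, with medians of 0.32 and 0.27 (camera adjusted p = 3.7e-14; adjusted p = 0.699 with an estimated correlation). Of 29 targets of ATF4, the factor of the integrated stress response, 24 were higher in both and none lower in both, with medians of 0.40 and 0.15 (camera adjusted p = 5.5e-17; adjusted p = 0.724 with an estimated correlation). Among these GDF15, a secreted stress cytokine gene, had ratios of 3.00 and 1.64, TRIB3 of 1.9 and 1.38, and SLC7A5 and SLC3A2, the 2 chains of an amino acid transporter, of 1.9 and 1.92 in MDA-MB-231 and 1.34 and 1.25 in BT549. Of 24 NF-kB targets and cytokines 18 were higher in both, with medians of 0.51 and 0.26 (camera adjusted p = 6.8e-16; adjusted p = 0.699 with an estimated correlation). IL1B and IL1A, the interleukin-1 genes, went from 143 to 1019 and from 68 to 455 units in MDA-MB-231. In BT549 IL1B went from 27 to 81 units, a ratio of 2.81 (1.13 to 7.82), and IL1A from 13 to 34 units, with an interval of 0.626 to 15.3. CSF3 and CSF2 had at most 19 units in BT549, and their intervals there spanned 1.

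Interferon-stimulated genes were lower. IFIT1, an antiviral RNA-binding protein gene (ENSG00000185745; chromosome 10, 89392546 to 89406487), had ratios of 0.446 (0.398 to 0.498) and 0.445 (0.356 to 0.553), IFIT2 of 0.490 and 0.536, IFIT3 of 0.550 and 0.513, OASL of 0.407 and 0.628, and IFI44L of 0.625 (0.364 to 1.02) and 0.323 (0.260 to 0.396). Of 27 measured members 15 were lower in both lines and 2 higher in both, with medians of -0.15 in MDA-MB-231 and -0.67 in BT549 (camera adjusted p = 2.7e-19; adjusted p = 0.699 with an estimated correlation). In MDA-MB-231 11 of the members were higher. IRF9 was among them at a log2 change of 1.46, but it shares its strand and position with another gene, and their summed units went from 3654 to 2840. IFIT1, IFIT2 and IFIT3 all overlap LIPA on the opposite strand, which had up to 4494 units and log2 changes of -0.51 and -0.39, so their counts are uncertain by the share of such reads.

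No single gene passed edgeR's quasi-likelihood test for treatment, in which the cell lines serve as the 2 pairs and leave 1 residual degree of freedom: 0 of 19927 genes had an adjusted p under 0.05, the lowest was 0.125, and 809 had an unadjusted p under 0.05 where chance gives 996. A two-sided exact permutation of 2 pairs cannot give a p under 0.5. limma-voom also called 0 genes (971 at an unadjusted p under 0.05), while DESeq2 called 97 (598 unadjusted), 37 higher and 60 lower. All 97 went in the same direction in both lines, but the test favours genes on which the lines agree, so this is no separate support. On the deposited values divided by 4, which puts 1 fragment at about 1 count, edgeR called 74, of which 57 were among the 97. DESeq2 was not rerun on the divided values. Its calls, here and in the lists below, rest on units that count 1 fragment about 4 times, so its p-values can be too small. The 74 were not all shared changes: EHF, for example, had log2 changes of -1.11 and 0.05. With adjustment over the list alone, edgeR's adjusted p was under 0.05 for 6 aryl hydrocarbon receptor targets, 4 NRF2 targets, 4 ATF4 targets and 8 NF-kB targets, all higher, and for 9 fatty acid genes, 4 cholesterol genes and 9 interferon-stimulated genes, all lower. DESeq2 called 3, 5, 4 and 1 of the same 4 lists higher, and 7, 3 and 4 of the same 3 lists lower. DESeq2 gave no adjusted p to 10431 of the 19927 genes, among them 10 of the 24 NF-kB members.

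**Figure D1:**
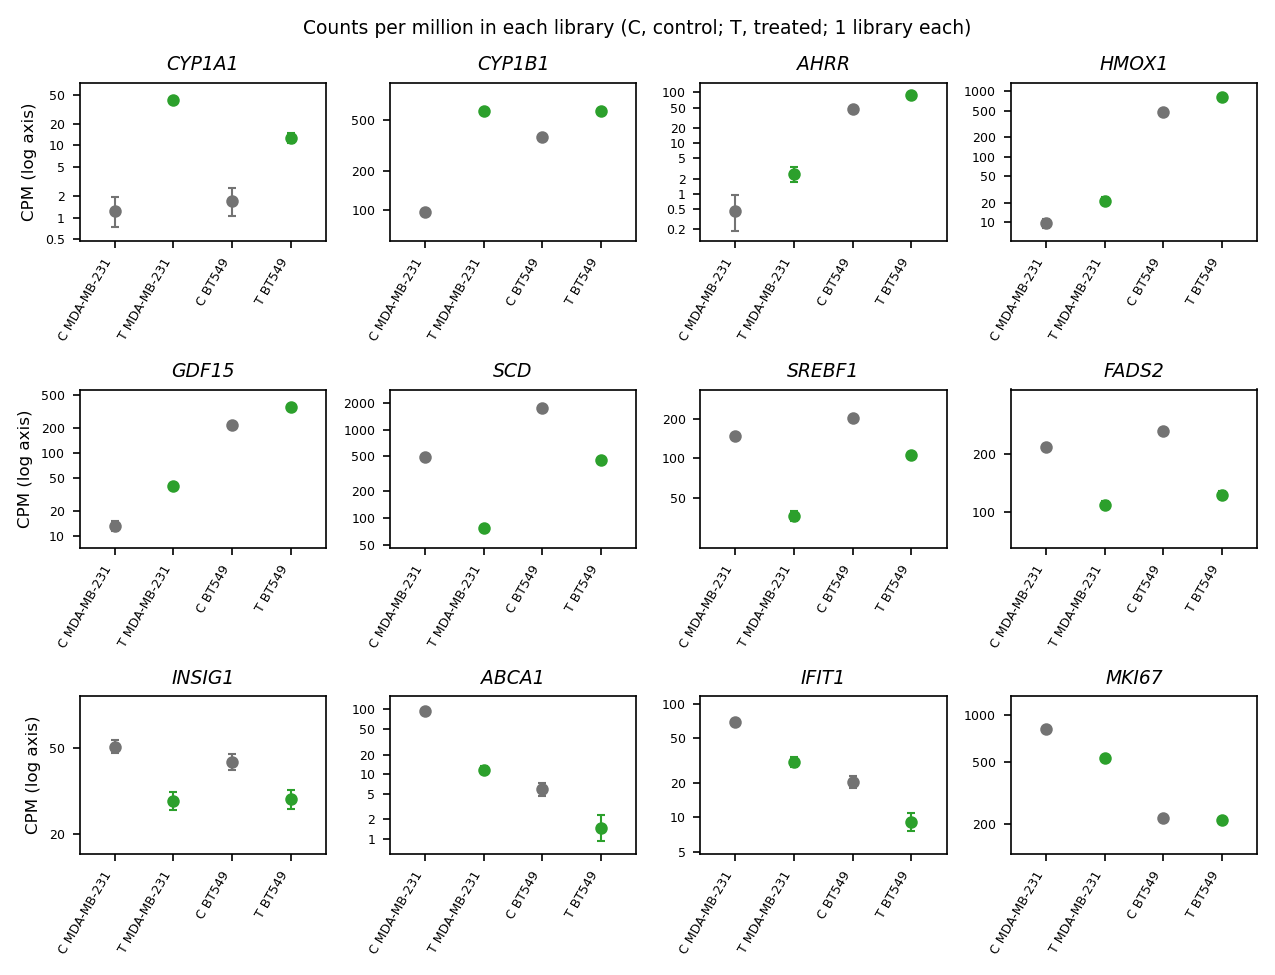
Scaled counts (CPM, log axis) of 12 genes in the 4 libraries, control in grey and treated in green, with exact 95% Poisson intervals on fragments as bars, which cover counting error only. In both lines CYP1A1, CYP1B1, AHRR, HMOX1 and GDF15 lie higher in the treated library and SCD, SREBF1, FADS2, INSIG1, ABCA1 and IFIT1 lower, while MKI67 is lower in treated MDA-MB-231 and differs by a ratio of 0.972 in BT549.

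By the smaller of the 2 lines' changes, the 12 genes highest in both, among genes with a symbol and a mean of at least 5 CPM in each line, also held BEST1, SHISA2, PRPF40B, RPL21P16, RPL21P75, MFSD11 and LPXN, and the 12 lowest also held RPL14P1, RPL21, MATN2, TIMP3, PPL and SENP3-EIF4A1. SHISA2 had log2 changes of 1.69 and 0.97, and LPXN, a focal adhesion protein gene, ratios of 2.74 and 1.61. TIMP3, an inhibitor of matrix metalloproteinases, had ratios of 0.541 and 0.534, MATN2, a matrix protein gene, of 0.460 and 0.529, and PPL, which encodes the desmosomal protein periplakin, of 0.514 and 0.542. BEST1 (ENSG00000167995; chromosome 11, 61950063 to 61964461), an anion channel gene, had the largest shared increase, with ratios of 52.8 (27.2 to 164) and 22.6 (19.8 to 25.9). It overlaps FTH1 on the opposite strand, which had up to 399474 units and log2 changes of 0.90 and 0.30, and the use of strand in counting is not given in the sources used here, so BEST1 is uncertain. MFSD11, PRPF40B and MATN2 overlap more abundant opposite-strand genes as well. RPL21 was lower, with ratios of 0.522 and 0.45, while its processed copies RPL21P16 and RPL21P75 were higher, with ratios of 3.29 and 3.40 in MDA-MB-231. Their summed units were 11545 and 11501 in MDA-MB-231 and 19114 and 16244 in BT549, so the split between near-identical copies is uncertain. RPL14P1, a copy of RPL14, went from 4029 to 654 units in MDA-MB-231 while the sum with RPL14 went from 25323 to 25858.

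Measures of RNA composition differed with treatment as well. At 4 rows on chromosome 21, of which 3 lie within the 18S ribosomal RNA genes of RefSeq on GRCh38, counts took 0.102% of the control and 0.179% of the treated MDA-MB-231 library, and 0.313% and 0.557% in BT549. Mitochondrial ribosomal RNA took 0.47% and 0.64% in MDA-MB-231 and 1.09% and 1.28% in BT549. Log2 fold changes correlated across genes with transcript length (Spearman's rho -0.25 in MDA-MB-231 and -0.06 in BT549) and with GC content (0.27 and 0.16), where genes are not independent replicates. Medians corrected for both were 1.99 and 0.73 for the aryl hydrocarbon receptor list, -0.49 and -0.32 for the fatty acid list and -0.12 and -0.69 for interferon-stimulated genes.

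In MDA-MB-231, 85 of 11380 genes with a mean of at least 5 CPM were higher by 2-fold or more and 65 were lower. Without genes that overlap another measured gene on the same strand these were 56 and 45. Here and below, the genes with the largest changes are those among genes with a symbol, and some rows with an identifier alone changed more. Beside CYP1A1 and BEST1 the largest increases were PEDS1-UBE2V1, ISY1-RAB43 and MFSD2B, and among genes without a same-strand partner IL24, a cytokine gene with a ratio of 8.41 (6.42 to 11.4), and IL1B, with 7.33 (5.19 to 10.8). SCG5, which encodes a secretory granule chaperone, had a ratio of 6.16 (4.08 to 9.81) and overlaps a read-through gene. Their summed units went from 236 to 754, a log2 change of 1.73. PEDS1-UBE2V1 and ISY1-RAB43 are read-through genes whose counts went from 0 to 1436 and from 0 to 1380 units, at least 125-fold and 120-fold higher against a floor of 3 fragments, and stand over their component genes. Summed with those genes, the units went from 16842 to 16066 and from 3252 to 3786, log2 changes of -0.01 and 0.28. MFSD2B went from 3 to 821 units, an interval of 37.9 to 8480, and overlaps FKBP1B. Summed with FKBP1B the units went from 24 to 867, a log2 change of 5.21. MFSD2B also overlaps WDCP, with up to 1039 units, on the opposite strand, so its counts are uncertain. ABCA1, the cholesterol efflux pump gene (ENSG00000165029; chromosome 9, 104781006 to 104928155), went from 5865 to 688 units, a ratio of 0.123 (0.104 to 0.143), and in BT549 from 307 to 79, a ratio of 0.256 (0.147 to 0.420). Other genes among the lowest were RPL17-C18orf32, a read-through gene with 822 and 0 units (at least 65.7-fold lower), SAMD12 with a ratio of 0.129, the pseudogene LSM12P1 with 0.199, and SCD, RPL14P1 and SREBF1. Summed with its component genes RPL17-C18orf32 had 20119 and 21274 units.

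Cell cycle genes were lower in treated MDA-MB-231. All 28 mitosis and G2/M genes were lower there, with a median of -0.42, below every one of 10000 random lists of matched expression, and examples were MKI67 with a ratio of 0.644 (0.626 to 0.663), TOP2A with 0.679, ASPM with 0.663 and DLGAP5 with 0.664. Such genes can move together, unlike those of random lists, so the rank is a description and not a test of treatment. Of 28 genes of the G1/S and DNA replication list 27 were lower, with a median of -0.40, among them CCNE2 at 0.629, TYMS at 0.639 and MCM4 at 0.733. CCNE2 overlaps opposite-strand genes with up to 5328 units. All 24 homologous recombination genes were lower, with a median of -0.34, among them RAD51AP1 at 0.619 and BRIP1 at 0.644. In BT549 the medians of these 3 lists were -0.04, 0.05 and 0.07, at percentiles 20.1, 93.9 and 92.1 of random lists. Over both lines camera called them lower (adjusted p = 1.7e-08, 1.6e-04 and 0.00476; adjusted p = 0.8 for each with an estimated correlation), and no member passed edgeR's or DESeq2's threshold. Metallothionein genes had ratios of 3.32 (MT1E), 2.70 (MT2A) and 2.76 (MT1X) in MDA-MB-231 and 1.11, 1.04 and 0.918 in BT549. Of the list of 8, 4 were higher and 2 lower in MDA-MB-231, with medians of 0.03 in both lines (1.34 and 0.2 over the 5 members that could be corrected for length and GC content), and it was not called (camera adjusted p = 0.0561). The length and GC trends named above are stronger in this pair of libraries.

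In BT549, 28 of 11233 genes were higher by 2-fold or more and 68 were lower, and without same-strand overlaps 11 and 44. Beside BEST1 and CYP1A1 the largest increase was ALDH1A1, a retinal-oxidizing aldehyde dehydrogenase gene, from 42 to 567 units, a ratio of 12.7 (7.33 to 29.6), against 1.94 (1.38 to 2.81) in MDA-MB-231. DUS4L-BCAP29, TBCE and IFI30 followed at 6.75, 4.03 and 3.52 and each overlaps another gene on its strand. Summed with their same-strand partners they had log2 changes of -0.01, -0.01 and -0.42, so no increase was seen over these loci. The noncoding gene PRAL had ratios of 3.51 in BT549 and 2.96 in MDA-MB-231, and ENTPD1 had 3.07, while the opposite-strand gene ENTPD1-AS1 had 0.232. PRAL overlaps XAF1, with up to 4113 units, on the opposite strand, so its counts are uncertain. Beside SCD and RPL14P1 the lowest genes were SNX22, a sorting nexin gene that overlaps PPIB on the opposite strand, from 991 to 53 units, and IGFBP5, a secreted binding protein of insulin-like growth factors, from 1191 to 139, a ratio of 0.115 (0.0785 to 0.163). They were followed by SENP3-EIF4A1, a read-through gene, at 0.168, ZFHX3-AS1 at 0.174, and ACKR3, an atypical chemokine receptor gene, at 0.309. Summed with its same-strand partners SENP3-EIF4A1 had a log2 change of -0.02. ZFHX3-AS1 overlaps ZFHX3, with up to 2472 units, on the opposite strand.

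Hypoxia and glycolysis genes were lower in treated BT549. All 19 hypoxia targets were lower, with a median of -0.52, and 20 of 21 glycolysis genes, with a median of -0.32, where MDA-MB-231 had medians of 0.01 and 0.00. Each BT549 median was below every one of 10000 random lists, again a description and not a test. Examples were PPP1R3C with a ratio of 0.445 (0.372 to 0.524), PFKFB4 with 0.507 (0.397 to 0.640) and PGK1 with 0.611 (0.586 to 0.636). CA9 and EGLN3 had at most 44 units in BT549 and intervals that spanned 1. VEGFA, the vascular growth factor gene, was 0.807 in BT549 and 2.42 (2.35 to 2.5) in MDA-MB-231. Over both lines camera called the lists lower (adjusted p = 5.9e-04 and 2.6e-04; adjusted p = 0.8 for both with an estimated correlation). Genes of 24 collagens and matrix proteins had medians of -0.27 in BT549 and -0.01 in MDA-MB-231 (camera adjusted p = 0.00731; adjusted p = 0.699 with an estimated correlation), with COL3A1 at 0.497 and COL1A2 at 0.736 in BT549, and the mean over members was 0.12, opposite in sign to the median and the test. The fibroblast and stroma markers, several of them the same collagens, had a median of -0.48 in BT549 and 0.24 in MDA-MB-231 and were not called (camera adjusted p = 0.187).

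**Figure D2:**
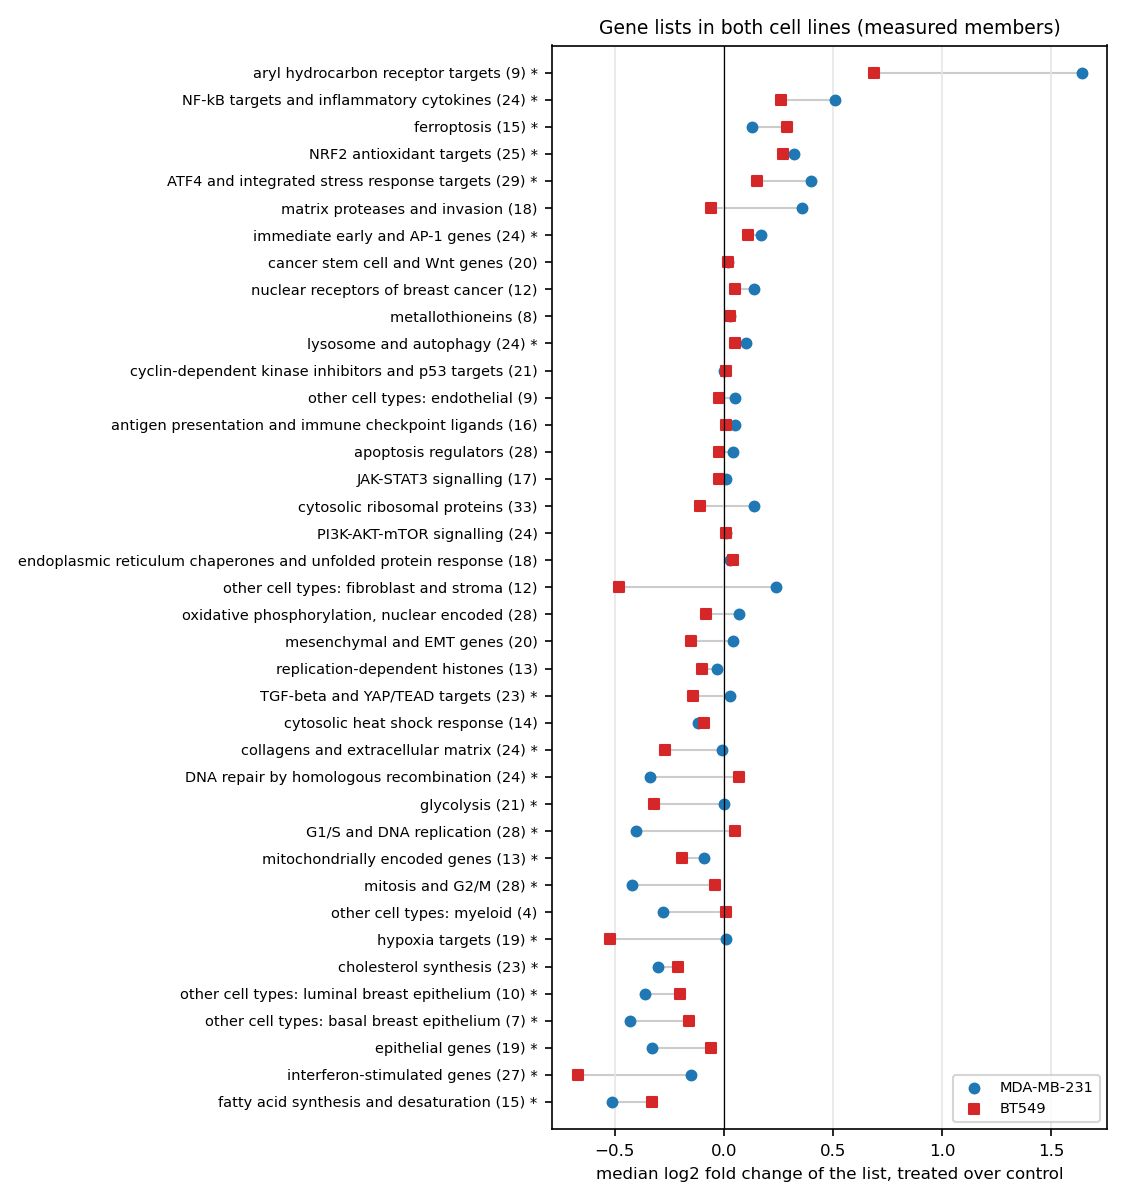
Median log2 fold change, treated over control, of 39 gene lists in MDA-MB-231 (blue circles) and BT549 (red squares), 1 library per group, with the number of measured members in parentheses and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The aryl hydrocarbon receptor list lies at 1.64 and 0.69 and the fatty acid list at -0.51 and -0.33, while the mitosis list lies at -0.42 and -0.04 and the hypoxia list at 0.01 and -0.52.

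The responses of the lines shared a small part. Across 10241 genes with at least 5 CPM in each line the log2 fold changes had Pearson's r of 0.15 and Spearman's rho of 0.14, a description across genes, which are not independent replicates. The comparisons share no library. Of 58 and 16 genes higher by 2-fold, 4 were higher in both where independent lists give 0.09, and of 39 and 43 lower, 5 were lower in both where 0.16 are given. Another 5 went opposite ways, and 55.2% of all genes had the same sign. Without same-strand overlaps r was 0.27 over 8512 genes, and 0 genes went opposite ways by 2-fold. Among genes with a symbol and at least 5 CPM in each line, those with the largest excess in MDA-MB-231 were MMP1, the interstitial collagenase gene, with ratios of 6.07 (5.77 to 6.38) and 0.780 (0.645 to 0.938), IFITM1, an interferon-induced antiviral gene, with 1.48 and 0.318, CYP1A1, CYP1B1, IRF9 with 2.75 and 0.714 and the overlap named above, and BMF, a pro-apoptotic gene, with 2.59 and 0.717 (0.502 to 1.02). ENTPD1-AS1 and SENP3-EIF4A1 were the others. On the side of BT549 they were RPL17-C18orf32, DUS4L-BCAP29, TBCE, IFI30, ENTPD1, LSM12P1, TREX2 with 0.341 and 1.25, and the zinc finger gene ZNF107 with 0.486 and 1.74. TREX2 overlaps HAUS7 on its strand, and their sum had a log2 change of -0.13 in MDA-MB-231. RPL17-C18orf32, DUS4L-BCAP29, TBCE and IFI30 also overlap genes on their strands. Their sums with these partners had log2 changes from -0.42 to -0.01 in BT549. None of these differences could be tested, since the interaction of line and treatment takes the last degree of freedom.

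**Figure D3:**
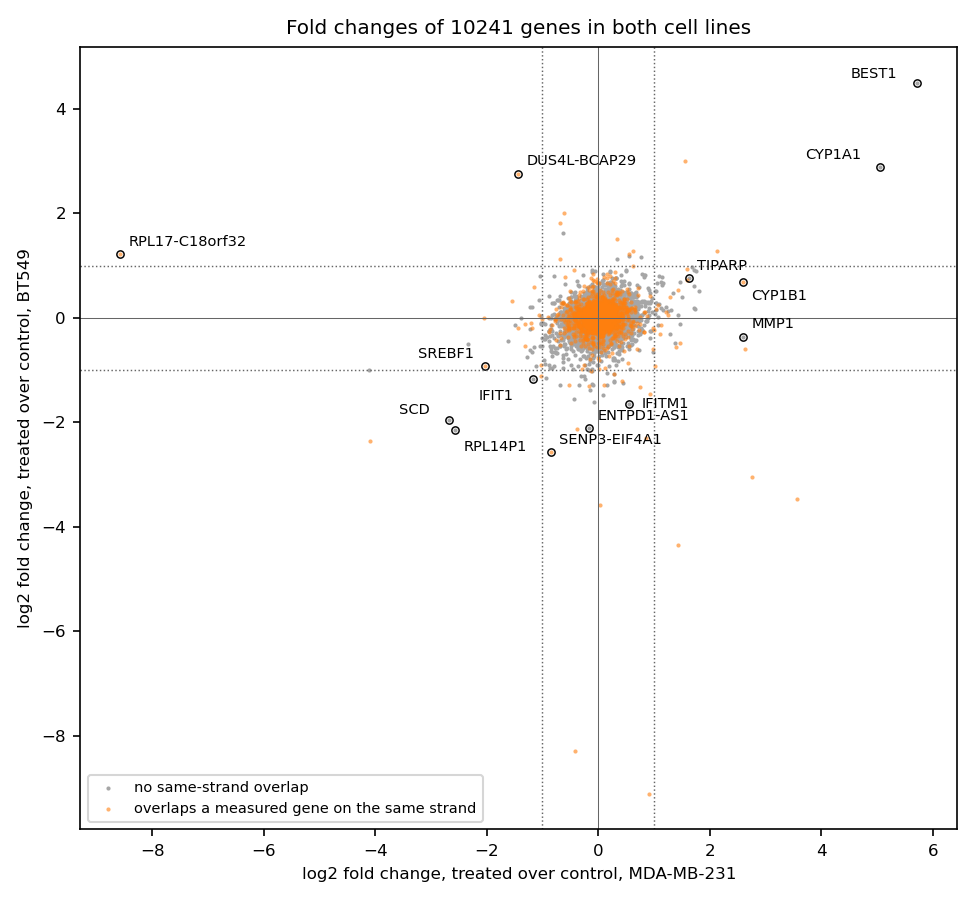
Log2 fold change, treated over control, in MDA-MB-231 (horizontal) and BT549 (vertical) for 10241 genes with a mean of at least 5 CPM in each line, 1 point per gene and 1 library per group. Orange points overlap another measured gene on the same strand and dotted lines mark 2-fold; BEST1 and CYP1A1 lie at the upper right and SCD and RPL14P1 at the lower left, and Pearson's r across genes is 0.15.

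Of the 40 fixed lists 39 were large enough to test, and camera with a preset correlation of 0.01 called 21, 7 higher and 14 lower. With an estimated correlation 0 were called, and fry, which asks whether the genes of a list move one way, called 0. Both rest on 1 residual degree of freedom, and the estimated correlation was 1 for the mitosis list. Their 0 calls therefore cannot decide for or against a list, and the 21 calls rest on the preset value. Beside those above, called higher were the immediate early and AP-1 genes (medians 0.17 and 0.11; adjusted p = 5.0e-04), lysosome and autophagy genes (0.10 and 0.05; adjusted p = 0.0025) and ferroptosis genes (0.13 and 0.29; adjusted p = 1.0e-06), each with adjusted p = 0.699 with an estimated correlation. IER3, a stress-induced survival gene, had ratios of 2.08 and 1.58 and DUSP6, a phosphatase of ERK kinases, of 1.44 and 1.40, while FOS was 1.22 and 0.476. The 4 ferroptosis members that were higher by edgeR adjusted over the list alone all belong to other called lists, HMOX1, FTH1 and FTL to the NRF2 list and PTGS2 to the NF-kB list. LPCAT3, a phospholipid acyltransferase gene, was lower at 0.430 and 0.654, and it overlaps opposite-strand genes with up to 3131 units. The lysosome list shares SQSTM1, and its member WIPI1 had 1.58 and 1.15. Corrected for length and GC content the MDA-MB-231 medians of these 3 lists were 0.09, 0.04 and 0.02. Called lower were mitochondrially encoded genes (-0.09 and -0.19; adjusted p = 0.0019; adjusted p = 0.8 with an estimated correlation), TGF-beta and YAP/TEAD targets (0.03 and -0.14; adjusted p = 0.00186; adjusted p = 0.766 with an estimated correlation), epithelial genes (-0.33 and -0.06; adjusted p = 0.00362; adjusted p = 0.699 with an estimated correlation), luminal markers (-0.36 and -0.20; adjusted p = 0.0119; adjusted p = 0.699 with an estimated correlation) and basal markers (-0.43 and -0.16; adjusted p = 0.00198; adjusted p = 0.778 with an estimated correlation). The keratin genes KRT8 and KRT18 had ratios of 0.797 and 0.765 in MDA-MB-231 and 0.766 and 0.780 in BT549, and CDH1, which encodes E-cadherin, went from 124 to 30 units in MDA-MB-231 and from 107 to 111 in BT549. Of the TGF-beta list 6 members were lower by edgeR adjusted over the list alone, among them CRIM1 at 0.619 and 0.698, BMP4 at 0.607 and 0.732 and ID2, which had at most 55 units in MDA-MB-231 and 0.529 in BT549, while SMAD7 was 1.55 and 1.31.

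The other 18 tested lists were not called (camera with a preset correlation). In some of them the lines went opposite ways: all 33 cytosolic ribosomal protein genes were higher in treated MDA-MB-231 and 28 were lower in treated BT549, with medians of 0.14 and -0.11, or 0.08 and -0.09 corrected for length and GC content (adjusted p = 0.513), and matrix protease and invasion genes had medians of 0.36 and -0.06 (adjusted p = 0.44), with 1 member higher and 3 lower by edgeR adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes had 0.07 and -0.08 (adjusted p = 0.953) and mesenchymal genes 0.04 and -0.15 (adjusted p = 0.306). The cytosolic heat shock list had -0.12 and -0.09 (adjusted p = 0.0561), replication-dependent histones -0.03 and -0.1 (adjusted p = 0.562) and nuclear receptors of breast cancer 0.14 and 0.05 (adjusted p = 0.624). Medians lay within 0.05 of 0 in both lines for endoplasmic reticulum chaperones (adjusted p = 0.347), p53 targets and cyclin-dependent kinase inhibitors (adjusted p = 0.953), apoptosis regulators (adjusted p = 0.996), antigen presentation (adjusted p = 0.673), PI3K-AKT-mTOR signalling (adjusted p = 0.953), JAK-STAT3 signalling (adjusted p = 0.953), stem cell and Wnt genes (adjusted p = 0.469) and endothelial markers (adjusted p = 0.602), and between libraries such small values can take either sign. Of 4 measured myeloid markers the medians were -0.28 and 0.01 (adjusted p = 0.452), and the lymphoid list, with 2 measured members, was not tested. Of 2280 Gene Ontology terms, a search added after the data were seen, camera called 11, 5 higher and 6 lower. Higher was, for example, G protein-coupled peptide receptor activity (medians 0.37 and 0.04, adjusted p = 0.00766; unadjusted p = 0.155 with an estimated correlation). Lower were, for example, negative regulation of viral genome replication (medians -0.1 and -0.21, adjusted p = 0.0057; unadjusted p = 0.121 with an estimated correlation) and collagen trimer (0.01 and -0.27, adjusted p = 0.0116; unadjusted p = 0.229 with an estimated correlation).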

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

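Of the tests reported here, those of read sharing and of few counts at overlapping genes, and those of length and GC content were chosen only after the results were seen.

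The results below stood out because MDA-MB-231 and BT549 moved in opposite directions, by at least 2-fold each way for a gene or with at least 80% of the members for a list. None of these differences was tested, since each line has 1 control and 1 treated library. Differences are log2 changes in MDA-MB-231 minus those in BT549. RPL17-C18orf32, a read-through gene, differed by -9.78, with 822 and 0 units in control and treated MDA-MB-231 and 364 and 869 in BT549. Summed with its component genes it had log2 changes of only 0.14 in MDA-MB-231 and -0.08 in BT549. SAMD12 differed by -4.32, with 963 and 117 units in MDA-MB-231 and 48 and 129 in BT549. DUS4L-BCAP29 differed by -4.19, with 1553 and 548 units and 200 and 1392, while its sum with its same-strand partners had log2 changes of -0.06 and -0.01. SNX22 differed by 5.67, with 57 and 154 units and 991 and 53. IGFBP5 differed by 9.16, a value that rests on a prior count, with 0 and 136 units in MDA-MB-231, at least 11.8-fold higher, and 1191 and 139 in BT549. COL3A1 differed by 4.98, with 4 and 91 units in MDA-MB-231, a ratio of 15.7 (interval 3.89 to 987) from about 1 fragment in the control, and 23745 and 12076 in BT549. The cytosolic ribosomal protein list differed by 0.25, with medians of 0.14 and -0.11, and of 0.08 and -0.09 after correction for length and GC content. The list of DNA repair by homologous recombination differed by -0.41, with medians of -0.34 and 0.07.

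Genes that overlap another measured gene on the same strand made up 16.9% of tested genes in either line but 32.7% of the 2-fold genes in MDA-MB-231 and 42.7% in BT549 (Fisher's exact p = 2.56e-06 and 2.27e-09). At a mean of at least 20 CPM the shares were still 28.6% against 16% in MDA-MB-231 and 45.8% against 16.3% in BT549 (Fisher's exact p = 0.0159 and 0.000641). This argues against a few counts in shallow libraries as the whole cause, more weakly in MDA-MB-231. All these Fisher's tests count the genes of 1 locus as independent, such as PTP4A1 and its same-strand partner in MDA-MB-231. Their p-values are therefore too small. Reads of 1 locus shared differently between gene models may account for a part: over 72 distinct loci the partners moved opposite to the gene in 49 (exact binomial p = 0.00294) and offset a median share of 0.6 of its change in units, with a wide interval of 0.02 to 0.83 (0.62 over 82 cases when a locus can count once per line). Where the gene held at least 50% of its locus the median offset was 0 over 25 distinct loci, and the partners moved opposite in 12. Partners with almost no units cannot offset a change: SREBF1 held 9067 of the 9071 same-strand units of its locus in control MDA-MB-231. Its locus there changed by -2.03 on the log2 scale, as the gene did. Where the partner had more units the offset could be large, as at PTP4A1 with 0.82 in MDA-MB-231. That median therefore cannot tell sharing from a change of the locus itself. A treatment effect on the choice of transcript, the biological alternative, was not tested.

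Cell-cycle genes were lower in treated MDA-MB-231, with a median of -0.42 for 28 mitosis genes, and the median was -0.04 in BT549. A length or GC trend in the MDA-MB-231 pair as the whole cause is argued against by the median of -0.4 after both trends were removed. A slower cycle of MDA-MB-231 under treatment may be the source, as a hypothesis from the same data that saw it, and a difference in density or growth between the 2 single cultures stays open, since the labels give neither. Whether the lines differ in this response was not tested.

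Fatty acid synthesis genes were lower in both treated lines, with medians of -0.51 and -0.33. A trend with length or GC content is argued against, since the weaker of the 2 corrected medians was -0.32. Lower activity of the liver X receptors, which drive SREBF1, SCD and ABCA1, may contribute, but the test left it open: over 8 further targets the median of the mean changes was -0.09, with an SE of the mean of 0.23, and without ABCG1, which is under the expression filter, it was -0.04 over 7 (SE of the mean 0.16). Members went both ways, with ABCG1 at 290 and 9 units in MDA-MB-231 and LPCAT3 lower in both lines, while TTC39B had log2 changes of 0.13 and 0.1. Both values lie above the bound of -0.1 set beforehand to reject this explanation, by less than their spread, and both that reading and keeping ABCG1 were decided after the value was seen.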

How the results depend on the processing

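The tests with values divided by 4, robust empirical Bayes, overlap-free genes or protein-coding genes with a symbol were chosen only after the results were seen. The number of genes that passed for treatment, 0 by edgeR, was 3 with library totals, 17 of 11699 at a mean of at least 5 CPM, 97 by DESeq2, 74 of 16078 with values divided by 4 and 3 of 16306 without same-strand overlaps. It was 0 with DESeq2 size factors, no filter, no block, limma-voom and robust empirical Bayes. Fewer genes were tested at 5 CPM, after division and without overlaps; otherwise the cause was not tested. The number that differed between lines stayed within 1.5 times 9955 under every alternative run. The 2-fold counts (higher and lower in MDA-MB-231, then in BT549) were 238, 217, 121 and 207 at 1 CPM, 33, 23, 4 and 20 at 20 CPM, which follows from the genes let in, and 56, 25, 18 and 24 with the authors' FPKM, where a pseudocount of 1 draws low values together. Without overlaps they moved to 56 higher in MDA-MB-231 and 11 and 44 in BT549, and with protein-coding genes that have a symbol to 16 higher in BT549. The correlation of the lines, 0.152, was 0.112 at 1 CPM, 0.227 at 20 CPM, 0.197 with FPKM, 0.273 without overlaps and 0.201 with protein-coding genes that have a symbol; the cause was not tested. The 21 lists called became 0 with an estimated correlation, which rests on 1 residual degree of freedom, and 22 with either other scaling. Each line alone leaves no residual degree of freedom, so medians are values with no test: they ranged from -0.40 to 0.05 for G1/S, -0.34 to 0.07 for homologous recombination, -0.52 to 0.01 for hypoxia and -0.14 to 0.03 for TGF-beta targets, the first 2 lower in MDA-MB-231 and the others in BT549. Against the plain mean of the lines' log2 changes, limma-voom's value had the other sign for IGFBP5 (-1.74), THY1 (-0.47), SPARC (-0.35), POSTN (-0.37), COL3A1 (-0.88), BGN (-0.1), SLC40A1 (-0.02) and VWF (0.19), each with few units in 1 line; edgeR's own fit was negative too for COL3A1 (-0.14) and THY1 (-0.44), and the cause was not tested. Of 182 named genes 40 passed by DESeq2, which gave 56 no adjusted p, and 0 by limma-voom. Depth limits genes near 12 units per library.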

Other observations

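The genes in this part were chosen after their values were seen, and no test of an explanation was run on them.

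VIPR1, a receptor gene for vasoactive intestinal peptide, went from 3215 to 16587 units in MDA-MB-231, a ratio of 5.37 (interval 4.98 to 5.8). In BT549 it went from 8 to 42 units, a ratio of 4.36 (1.04 to 45.9) from about 2 fragments in the control. Its edgeR adjusted p was 0.125 and its DESeq2 adjusted p 7.3e-27, both on deposited units and not on fragments. In MDA-MB-231 ASB2 went from 163 to 914 units. MYLIP, a ubiquitin ligase gene, had log2 changes of -1.80 and -1.01. INHBB, an activin subunit gene, had -0.99 and -1.12, and CD24, a surface glycoprotein gene, -0.80 and -0.93.

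Transcripts of liver secretory proteins were present in MDA-MB-231: ALB had 832 units in the control and 1027 in the treated library, SERPINA1 3045 and 4550, TF 320 and 457, and APOB 203 and 217. In BT549 ALB had 13 and 0 units and APOB 0 in both. The deposited table also holds 3 libraries named for the liver line Huh7, which were not used here, and whether these reads are expression of MDA-MB-231 or carry-over from another library was not tested. In MDA-MB-231 the prostate genes KLK3 and FOLH1 went from 210 and 97 units to 0, at least 16.8-fold and 7.76-fold lower. Stromal genes went both ways in MDA-MB-231: DCN went from 0 to 40 units and SPARC from 57 to 182, while COL1A2 went from 1137 to 354. In BT549 DCN had 21 and 6 units, SPARC 4790 and 3400 and COL1A2 73632 and 55402. ANPEP had 22 and 47 units in MDA-MB-231 against 133080 and 145577 in BT549.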
